A study of Mus musculus with 11 samples.

How the data were processed

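RNA from alveolar macrophages, the phagocytes that live in the air spaces of the lung, was measured by bulk RNA-seq in 11 libraries from wild-type C57BL/6 mouse pups. Per the labels, the cells were sorted from lung homogenates by flow cytometry on postnatal day 7. Pups of the exposed groups had breathed 95% oxygen (hyperoxia) from postnatal day 1 to day 5, and the others were kept in normoxia. The libraries fall into 4 groups by oxygen and sex, with 3 normoxia male, 3 normoxia female, 2 hyperoxia male and 3 hyperoxia female libraries. The 2 hyperoxia male libraries carry the replicate numbers 2 and 3. The labels do not say whether the replicates of a group are separate animals or pools, so the p-values measure the spread between these libraries, which may be partly technical.

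The deposited table holds 1 whole-number read count per Ensembl gene and library, not normalized. Per the labels' protocols, libraries were made with a low-input full-length cDNA kit, the first 8 nucleotides were unique molecular identifiers, and these and the adapter were trimmed. Fragments shorter than 250 bp were removed from some libraries, which were resequenced, and the labels do not make clear which. Nothing in the sources used here says that the identifiers were used to collapse duplicate reads, or that the counting used strand. Reads of overlapping, antisense or near-identical genes can therefore be split between them. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, STAR 2.7.9, Salmon 1.10.1, R 4.3.2 and DESeq2 1.42, with the mouse build mm39. The role of each tool and the annotation release are not given in the sources used here. Symbols were looked up by Ensembl identifier in a supplied gene name table, which matched 51884 of 57180 identifiers (90.7%). No coordinates are given, because the reference annotation at hand (GENCODE M21) is of another build, and it served for exon lengths and gene types only.

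Total counts ran from 18087948 (normoxia male replicate 3) to 32579468 (normoxia female replicate 1). The floor used here, 3 counts in a library, ran from 0.0880 CPM (counts relative to the scaled library size) in hyperoxia female replicate 2 to 0.160 CPM in normoxia male replicate 1. The floor covers counting error only, while each SD and SE includes the spread between libraries. Each library was counted as 1 replicate, as the labels name it. No pair of libraries of a group agreed within sampling noise, the smallest chi-square per gene being 19.0, so no sign of 1 library deposited more than once was seen. Libraries made apart from 1 pool of RNA would also differ by more than that noise, so this does not show that the replicates are separate animals.

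Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with the 4 groups (a count of about 10 in the smallest group and a total of 15), which left 19948 genes, 669 of them without a symbol. Libraries were scaled by TMM. A model with 1 mean per group was fitted to all 11 libraries with edgeR's robust quasi-likelihood method, and 7 contrasts were tested: hyperoxia minus normoxia in males, in females and averaged over the sexes, female minus male in normoxia, in hyperoxia and averaged over the oxygen groups, and the interaction, which is the female response minus the male response. Every adjusted p of a gene is a Benjamini-Hochberg value over the genes tested in its contrast, and a gene was counted as changed under 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F-test.

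The 28 gene lists, fixed at the same time as the tests, hold 374 genes, and 353 of these genes were measured. The lists cover alveolar macrophage identity, cell cycle, p53 targets, antioxidant genes of the NRF2 pathway, inflammatory cytokines, type I interferon response, cholesterol synthesis, lipid handling, glycolysis and hypoxia, oxidative phosphorylation, repair and alternative activation, MHC class II, efferocytosis and complement, iron handling, immediate early genes of tissue dissociation, Y-linked genes, X inactivation and escape, and markers of monocytes, neutrophils, interstitial macrophages, dendritic cells, eosinophils with basophils and mast cells, B cells, T and NK cells, erythroid cells, epithelium, endothelium and mesenchyme. Lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists tested. The list of eosinophil, basophil and mast cell markers had 2 measured members and was not tested. Camera compares a list with all other genes, and was repeated with a correlation estimated from the data. Fry, which tests whether the members of a list move on balance in 1 direction, was also run. For each list the number of members past the test over all genes stands beside the number adjusted over the list alone.

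The rule for named genes, the groups, the tests and the alternatives listed first below were fixed before the data were examined. For each contrast, the rule names up to 10 changed genes per direction with the largest log2 fold changes, at a mean log2 CPM of at least 1 and with every library of one side above every library of the other. Predicted genes, pseudogenes and genes with no symbol were passed over, 8 of them in the averaged hyperoxia contrast. Where fewer than 10 genes qualified, up to 5 per direction with the smallest p are named as not past the test. Of each list, up to 4 changed members are named, or else at most the member with the smallest p, and Xist with 4 Y-linked genes served to check the labels. For 1 gene that the rule names, the result is not reported here, though the gene stays in all counts.

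The fit was tested on simulated counts for 19948 genes with the mean levels, library sizes and edgeR dispersions of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold per contrast, all drawn from genes above 4 CPM. For 2-fold changes, 22% were recovered in the male, 42% in the female and 87% in the averaged hyperoxia contrast. For the sex contrasts these shares were 40% in normoxia, 31% in hyperoxia and 77% on average, and 3% for the interaction. For 4-fold changes the share was 68% for the interaction and between 94% and 100% for the others. Between 2.31% and 6.60% of calls were false in these simulated counts. The genes were drawn independently, without differences between libraries that many genes share, so these shares may not carry over to the real libraries. In the averaged hyperoxia contrast, camera called 5 of 5 simulated lists of independent genes that were shifted 1.5-fold, and 0 of the other lists among the 20 simulated.

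The alternatives tried were size factors of DESeq2 1.42.0 in place of TMM, no expression filter, the DESeq2 Wald test, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. Chosen after seeing the data were a term for the 4 libraries in which most genes were detected, a fit without these 4 libraries (which leaves 1 hyperoxia female library, assumed to vary like the other groups), protein-coding genes only, an offset per library that depends on exon length, and an exact permutation of the mean level of each list. Every identifier in the table is an Ensembl gene, and all 11 columns of counts were used.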

Results

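The series measured RNA of alveolar macrophages from newborn mice and, by its title, asked about sex as a biological variable in the response to high oxygen. The 11 libraries are written here by oxygen group (N for normoxia, H for hyperoxia), sex (M or F) and replicate number, so that HF2 is hyperoxia female replicate 2. There were 3 libraries each for NM, NF and HF and 2 for HM. Total counts were 21572925, 26757489 and 18087948 for NM1 to NM3 and 32579468, 30209539 and 24146144 for NF1 to NF3. They were 25151172 and 26687549 for HM2 and HM3, and 30304004, 29787390 and 24484375 for HF1 to HF3. Genes with at least 1 count numbered 26856 to 30173 in 7 libraries and 35530, 33158, 35449 and 34236 in NM3, NF3, HF2 and HF3. In these 4 libraries chemoreceptor genes, the odorant and vomeronasal receptors, summed to 144 to 273 CPM, against 44.8 to 74.1 CPM in the others. The identifier with most counts took between 4.80% (HF2) and 20.8% (NM3) of a library, and mitochondrial genes took 5.77% to 9.45%.

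The sex-linked genes followed the labels in every library. Xist, the RNA that coats the inactive X chromosome, stood at 453 ± 15.6 CPM (SD, n = 3) in normoxia females and 562 ± 154 CPM (SD, n = 3) in hyperoxia females, against 0.886 ± 0.678 CPM (SD, n = 3) and 0.442 ± 0.0435 CPM (SD, n = 2) in the males of those groups. The Y-linked genes measured in males were Ddx3y (63.7 ± 12.7 and 72.8 ± 9.42 CPM), Eif2s3y (48.5 ± 4.96 and 41.3 ± 1.52 CPM), Kdm5d (25.6 ± 3.70 and 23.8 ± 4.61 CPM) and Uty (16.2 ± 1.28 and 15.5 ± 1.47 CPM, all SD, n = 3 in normoxia and 2 in hyperoxia). Their group means in females were 0.0406 to 0.461 CPM. Reads of Ddx3y, Eif2s3y, Kdm5d and Uty can be shared with their X-linked copies, and the female libraries held 0 to 32 counts of each, so no fold is given for them.

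**Figure D1:**
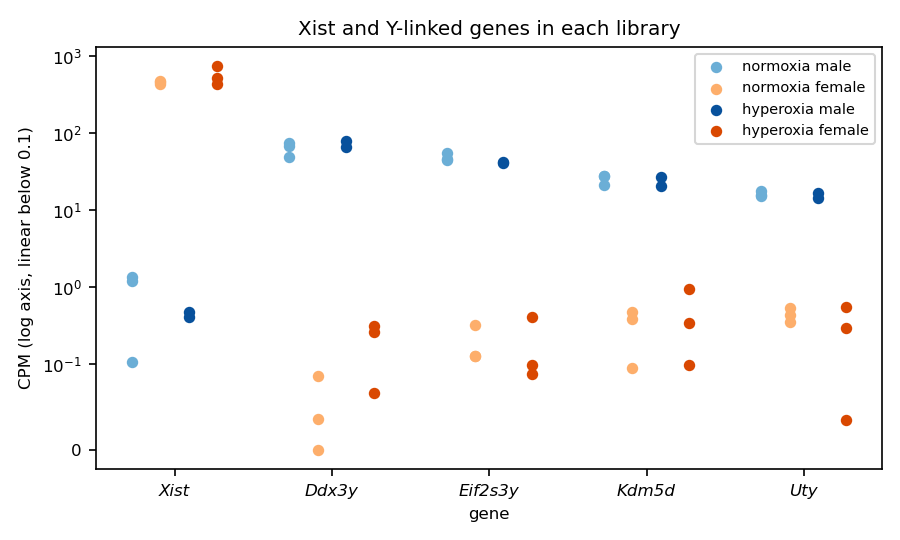
Level of Xist and of 4 Y-linked genes in each library, in CPM on a log axis that is linear below 0.1, by oxygen group and sex. Xist lay between 436 and 734 CPM in the 6 female libraries and at or below 1.34 CPM in the 5 male ones.

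Hyperoxia was first compared with normoxia over both sexes. Fabp1, a fatty acid carrier, was lower after hyperoxia. It stood at 60.9 ± 6.34 and 52.3 ± 9.74 CPM (SD, n = 3 each) in normoxia males and females and at 9.33 ± 1.19 (SD, n = 2) and 11.2 ± 5.69 CPM (SD, n = 3) after hyperoxia. Ctsk, a lysosomal cysteine protease, was also lower, at 144 ± 48.0 and 138 ± 68.0 CPM against 43.7 ± 4.09 and 36.8 ± 6.50 CPM. Itgam, the integrin chain CD11b of myeloid cells, was higher, at 15.7 ± 6.38 and 26.2 ± 0.747 CPM in normoxia and 59.4 ± 12.6 and 63.0 ± 23.0 CPM in hyperoxia. Ecm1, a secreted matrix protein, stood at 3.35 ± 1.02 and 4.14 ± 0.459 CPM against 14.4 ± 0.286 and 13.2 ± 3.89 CPM (SD, same n).

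In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 141 of 19948 genes changed with hyperoxia over both sexes, 108 higher and 33 lower. A total of 1621 genes had an unadjusted p under 0.05 where 997 would be expected with no effect. Of the 141, 133 had a mean log2 CPM of at least 1 and hyperoxia libraries all above or all below the normoxia libraries of their sex. The largest rises, as log2 fold change ± SE, were those of Ecm1 (1.89 ± 0.20), Fcna (1.87 ± 0.34), a ficolin that binds sugars on microbes, Pkp2 (1.75 ± 0.32), a desmosome protein, Slc22a4 (1.75 ± 0.30), an organic cation transporter, and Ccnd1 (1.74 ± 0.22), cyclin D1. They were followed by Cd276 (1.65 ± 0.21), Treml2 (1.64 ± 0.32), Itgam (1.59 ± 0.21) and Atp2a3 (1.53 ± 0.18), a calcium pump. Their adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 0.000237 for Ecm1 to 0.0207 for Treml2. The largest falls were those of Cxcr1 (-2.69 ± 0.46), a chemokine receptor, Fabp1 (-2.47 ± 0.24), Patj (-2.11 ± 0.21), a scaffold of cell polarity, and Pdk4 (-2.09 ± 0.29), a kinase that shuts off pyruvate dehydrogenase. Next came Ucp3 (-2.03 ± 0.28), a mitochondrial carrier, Gpd1 (-1.84 ± 0.33), glycerol-3-phosphate dehydrogenase, Ctsk (-1.81 ± 0.25), Igflr1 (-1.80 ± 0.31), Snord21 (-1.64 ± 0.32), a small nucleolar RNA, and Cfb (-1.57 ± 0.28), complement factor B. Here the adjusted p of the same test ran from 0.000158 for Fabp1 and Patj to 0.0249 for Snord21. The count was 36 without HM3, 48 without HM2, 63 without HF2, 65 without NF1 and 80 without NF2. Without NM3, NF3, HF2 and HF3 together, which leaves HF1 as the 1 hyperoxia female library, assumed to vary like the other groups, it was 23, of which 19 were among the 141, with 10 higher and 13 lower, so the lean toward higher genes was not seen there. Of the 28 named genes that passed, Ecm1, Ccnd1, Cd276, Itgam, Atp2a3, Fabp1, Patj, Pdk4, Ucp3 and Ctsk passed with each library left out in turn. Calls lost among the 28 numbered 16 without HM3, 13 without HM2, 9 each without NF1, NF2 and HF2, 5 without HF1, 4 each without NM1 and HF3, 2 without NM3 and 1 each without NM2 and NF3.

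**Figure D2:**
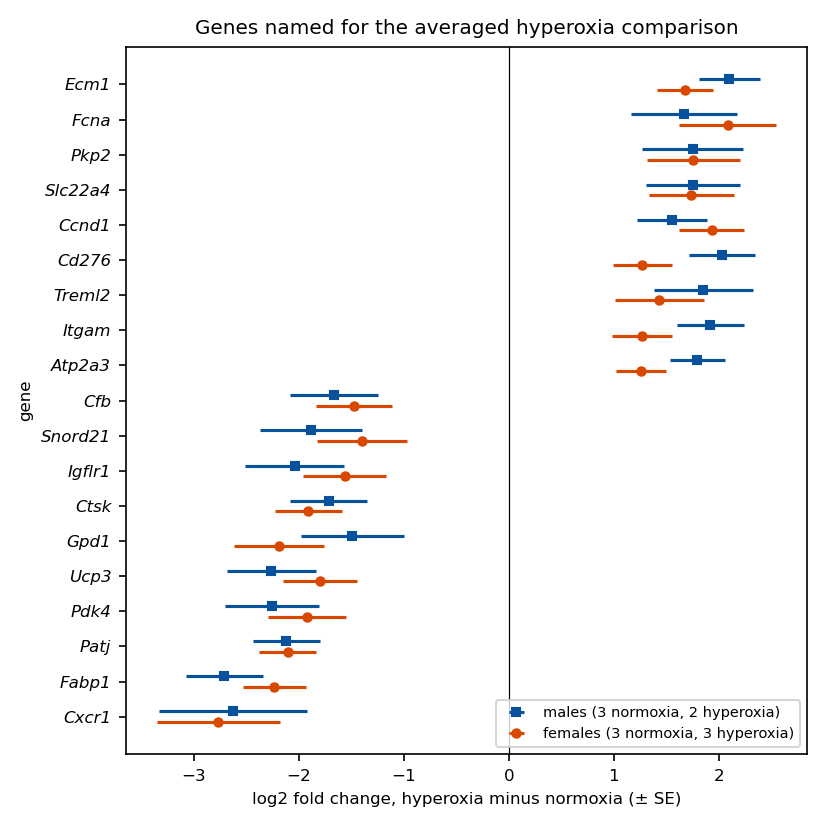
Log2 fold change (hyperoxia over normoxia, ± SE) of 19 genes with the largest changes over both sexes, in males (squares, 3 normoxia and 2 hyperoxia libraries) and females (circles, 3 and 3). Every gene lies on the same side of 0 in both sexes.

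Among alveolar macrophage identity genes, 6 of 26 measured fell after hyperoxia and none rose, with 9 lower when adjusted over the list alone. The largest falls besides Fabp1 and Ctsk were those of Fabp4 (-1.53 ± 0.31), a fatty acid carrier, and Cidec (-1.35 ± 0.22), a protein of lipid droplets (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0377 and 0.00901). The other members that passed were Krt79 (-1.32) and Ear1 (-0.98), named after their values were seen. Other members, also picked after their values were seen, did not pass, such as Siglecf (-0.69), Pparg (-0.20), Lpl (-0.06), Itgax (-0.06), Mrc1 (0.01) and Marco (0.18). The list median was -0.32 (SD 0.66 over members), with 3 of 26 members above 0 (camera adjusted p = 7.36e-11). It had adjusted p = 0.556 with an estimated correlation. Cell cycle genes were all higher, 24 of 24, with a median of 0.59 (SD 0.16, camera adjusted p = 3.7e-20), and adjusted p = 0.556 with an estimated correlation. Of them 3 passed over all genes, namely Rrm2 (0.83 ± 0.18), a subunit of ribonucleotide reductase, Aurka (0.75 ± 0.15), a mitotic kinase, and Bub1 (0.74 ± 0.16), a checkpoint kinase. Their edgeR quasi-likelihood, Benjamini-Hochberg adjusted p were 0.0392, 0.0315 and 0.0403, and 19 cell cycle genes passed when adjusted over the list alone. Both list calls held with each library left out in turn and without the 4 libraries with most genes detected, where HF1 alone stood for hyperoxia females.

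Markers of other cells moved in both directions. Of 8 endothelial genes, all lay below 0 (median -0.71, SD 0.24, camera adjusted p = 0.000239, and adjusted p = 0.556 with an estimated correlation). None passed the test over all genes, and 1 was lower when adjusted over the list alone. Erythroid genes also lay below 0, 6 of 6 (median -1.30, SD 0.20, camera adjusted p = 0.0219, and adjusted p = 0.647 with an estimated correlation), with none past the gene test on either adjustment. The erythroid call was lost without NM1 (-0.94), NM3 (-1.39), NF3 (-0.49) or HM2 (-0.91). All 8 monocyte markers lay above 0 (median 0.79, SD 0.33, camera adjusted p = 0.00297, and adjusted p = 0.556 with an estimated correlation). So did all 6 interstitial macrophage markers (median 0.93, SD 0.41, camera adjusted p = 0.0121, and adjusted p = 0.556 with an estimated correlation). In each of these lists 0 genes passed over all genes and 2 when adjusted over the list alone. The monocyte call was lost without NM2 (0.60) and the interstitial one without NM2 (0.83) or HM2 (0.54). With the calls kept, the medians without HF2 were 0.36 for monocyte markers (7 of 8 above 0) and 0.30 for interstitial ones. The erythroid median was -2.24 without HM3, and the endothelial one -0.39 without NM3, -1.16 without HM2 and -1.08 without HF3. Epithelial genes had a median of 0.42 (SD 0.47, 12 of 14 above 0, camera adjusted p = 0.00284, and adjusted p = 0.556 with an estimated correlation). Of them Etv5, a transcription factor, rose (1.08 ± 0.22, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0341), and 2 were higher and 1 lower when adjusted over the list alone. The epithelial call was lost without HM2 (0.26).

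Further lists that passed held few changed members. Efferocytosis and complement genes had a median of 0.47 (SD 0.73, 11 of 16 above 0, camera adjusted p = 0.0113, and adjusted p = 0.556 with an estimated correlation). Among them Msr1, a scavenger receptor, rose (1.13 ± 0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00901), and 3 were higher when adjusted over the list alone. Type I interferon genes had a median of 0.35 (SD 0.70, 13 of 17 above 0, camera adjusted p = 0.0204, and adjusted p = 0.647 with an estimated correlation). The median was 0.13 for cholesterol synthesis genes (SD 0.11, 18 of 19 above 0, camera adjusted p = 0.0219, and adjusted p = 0.757 with an estimated correlation) and 0.05 for repair genes (SD 0.72, 10 of 17 above 0, camera adjusted p = 0.0365, and adjusted p = 0.556 with an estimated correlation). None of these passed the gene test over all genes, and when adjusted over the list alone 3 repair genes were higher. The interferon call was lost without NM2 (0.25), NM3 (0.32) or HF2 (-0.02), and the efferocytosis call without NM3 (0.54). Cholesterol genes lost theirs without NM3 (0.06), NF3 (0.11), HM2 (0.15), HF1 (0.09) or HF2 (0.11), and repair genes without NM2 (0.21), NM3 (0.10), NF2 (0.08), HM3 (0.06) or HF2 (0.06). With the calls kept, medians moved by over 1.5 times for efferocytosis genes without HM2 (0.17) or HF2 (0.15), for interferon genes without HM3 (0.59) or HF3 (0.55) and for cholesterol genes without NM2 (0.21) or HF3 (0.20). For repair genes they did so without NF1 (0.12), HM2 (0.12), HF1 (0.14) or HF3 (0.13). Apart from the identity, cell cycle and endothelial lists, no list passed without the 4 libraries with most genes detected (HF1 alone for hyperoxia females), and fry gave adjusted p of at least 0.127 for all 27 lists.

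The other lists did not pass camera over both sexes, with medians of 0.15 for p53 targets (camera adjusted p = 0.0873), 0.06 for antioxidant genes, -0.14 for inflammatory cytokines, and -0.02 for lipid handling. They were 0.02 for glycolysis and hypoxia, -0.10 for oxidative phosphorylation, and -0.04 for MHC class II, and -0.04 for iron handling, 0.02 for immediate early genes, 0.07 for Y-linked genes and 0.01 for X inactivation and escape. Medians were 0.03 for neutrophil markers, 0.28 for dendritic, 0.27 for B, 0.51 for T and NK cell markers and -0.24 for mesenchyme, all with camera adjusted p of 0.091 or more. The mean and the test differed in sign from the median for iron handling (mean 0.07, test up), and for neutrophil markers (mean -0.16, test up) and X-linked genes (mean -0.04, test up) the mean alone did. Of these lists, 1 member passed over all genes, Mmp8, a collagenase of neutrophils (1.08 ± 0.22, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0298). When adjusted over the list alone, 2 p53 targets, 1 glycolysis, 1 iron handling, 1 immediate early, 1 Y-linked and 1 dendritic gene were higher and 2 mesenchyme genes lower. On that adjustment lipid handling had 2 higher and 2 lower, and neutrophil markers 2 higher and 1 lower. Eosinophil, basophil and mast cell markers were represented by Ms4a2 (0.03) and Gata2 (-0.42). Among members of smallest p that did not pass were Slc40a1 (0.95 ± 0.21), the iron exporter, Spp1 (0.86 ± 0.21), osteopontin, Scd1 (0.98 ± 0.23), a fatty acid desaturase, and Phlda3 (0.69 ± 0.17), a p53 target, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.0504 to 0.0841.

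**Figure D3:**
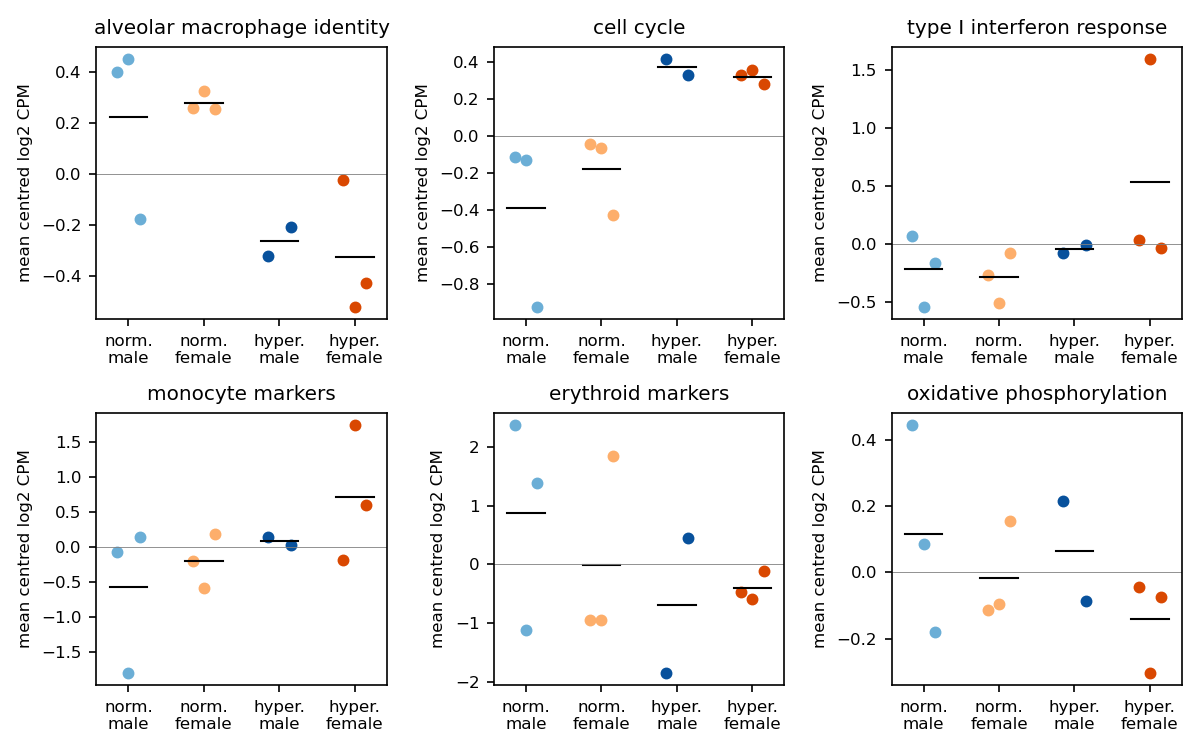
Mean centred log2 CPM of the members of 6 lists (alveolar macrophage identity, cell cycle, type I interferon, monocyte, erythroid and oxidative phosphorylation genes) in each library, with a line at each group mean. Library HF2 lies at 1.59 for interferon and 1.74 for monocyte genes, and NM1 at 2.37 for erythroid genes.

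In males alone, hyperoxia raised 6 genes and lowered 2, given as log2 fold change ± SE over 3 normoxia and 2 hyperoxia libraries. Ecm1 (2.10 ± 0.29), Cd276 (2.03 ± 0.31) and Baiap2 (1.94 ± 0.28), an adaptor of the actin skeleton, rose. So did Itgam (1.92 ± 0.32), Atp2a3 (1.80 ± 0.26) and Ptgs1 (1.59 ± 0.27), cyclooxygenase 1, while Fabp1 (-2.71 ± 0.36) and Patj (-2.12 ± 0.32) fell. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.016 for Ecm1, Baiap2, Atp2a3 and Fabp1 to 0.0466 for Ptgs1. An unadjusted p under 0.05 was found for 1098 genes. Next by p, and not past the test, came Lpcat1 (1.41), Alcam (1.31), Raet1d (1.46), Pcx (1.75) and Nfe2 (1.27). Among lower genes these were Ucp3 (-2.26), Pdk4 (-2.25), Slc9a4 (-1.47), Crim1 (-1.48) and Ctsk (-1.72), with adjusted p of the same edgeR quasi-likelihood test from 0.0525 to 0.146. The count was 0 without HM3, 18 without NF3 and 19 without NM1, against 83 with DESeq2. It was 3 without HM2 (Baiap2, Atp2a3 and ENSMUSG00000119851) and 5 without NM3 (Ecm1, Atp2a3, Fabp1, Patj and Palm), ENSMUSG00000119851 and Palm being named after their values were seen. Without NM3, NF3, HF2 and HF3 together it was 16, with 4 higher and 12 lower. None of the 8 genes passed with every library left out in turn.

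For lists in males, cell cycle genes were higher (median 0.73, SD 0.19, 24 of 24 above 0, camera adjusted p = 4.86e-17) and identity genes lower (median -0.30, SD 0.70, 6 of 26 above 0, camera adjusted p = 1.79e-05), each with adjusted p = 0.697 with an estimated correlation. Fabp1 was the 1 identity gene past the test over all genes, and 5 identity genes were lower and 13 cell cycle genes higher when adjusted over the list alone. Endothelial (-1.0, SD 0.35), mesenchyme (-0.99, SD 0.85) and erythroid genes (-1.79, SD 0.11) had medians below 0 and passed camera. They had adjusted p = 0.697, 0.697 and 0.719 with an estimated correlation. Cholesterol synthesis (0.19, SD 0.17), repair (0.19, SD 0.63), efferocytosis (0.51, SD 0.53) and epithelial genes (0.52, SD 0.59) had medians above 0 and passed camera. They had adjusted p = 0.759 for cholesterol and 0.697 for the others with an estimated correlation. Of these 7 lists none had a member past the test over all genes, and adjusted over the list alone 2 mesenchyme genes were lower and 1 repair, 1 efferocytosis and 2 epithelial genes higher. Calls were lost without NM3 for endothelial (-0.47), mesenchyme (-0.27), erythroid (-1.84), cholesterol (0.05), repair (0.26) and efferocytosis genes (0.33). They were lost without NM2 for repair (0.48), efferocytosis (0.46) and epithelial genes (0.28), and without HM2 for erythroid (-0.97), cholesterol (0.27), efferocytosis (0.18) and epithelial genes (0.17). Further losses came without HM3 for endothelial (-0.76) and mesenchyme genes (-0.38), and without NM1 for erythroid genes (-0.99). With the calls kept, medians moved by over 1.5 times for identity genes without NM2 (-0.17) or NM3 (-0.46) and for cholesterol genes without NM2 (0.37). They did so too for repair genes without HM2 (0.48), endothelial genes without HM2 (-1.82) and erythroid genes without HM3 (-3.48).

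In females alone, hyperoxia raised 3 genes and lowered 5, over 3 and 3 libraries. Ccnd1 (1.93 ± 0.31), Ecm1 (1.67 ± 0.27) and St14 (1.58 ± 0.26), the membrane protease matriptase, rose. Fabp1 (-2.23 ± 0.30), Patj (-2.11 ± 0.27), Ctsk (-1.91 ± 0.32), Slc9a4 (-1.60 ± 0.25), a sodium and proton exchanger, and Sorbs3 (-1.49 ± 0.24), an adaptor of cell adhesion, fell. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.011 for Patj to 0.0422 for Ctsk. An unadjusted p under 0.05 was found for 904 genes. Not past the test came Pstpip1 (1.23), Atp2a3 (1.26), Ptgs1 (1.29), Ldhb (1.21) and Neil3 (0.89). Lower, and not past it, were Syn1 (-1.67), Ank1 (-1.17), Mtmr7 (-1.36), Slpi (-1.66) and Pdk4 (-1.92), with adjusted p of the same edgeR quasi-likelihood test from 0.0832 to 0.0948. The count was 0 without HF2 or HF3, 14 without NM1, 16 without NM3 and 24 without NM2, against 84 with DESeq2. Fabp1 and Patj were called alone without NF1 (2 genes), with Ctsk without NF2 (3), with Slc9a4 and Csf3r without NF3 (4), and with Ccnd1, Slc9a4 and Slpi without HF1 (5). Without NM3, NF3, HF2 and HF3 the hyperoxia female group is HF1 alone, so that count, 2 (Zfp969 and ENSMUSG00002075931, named after their values were seen), is no replicated check of the 8.

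Female cell cycle genes were higher (median 0.51, SD 0.16, 24 of 24 above 0, camera adjusted p = 5.76e-12) and identity genes lower (median -0.36, SD 0.66, 2 of 26 above 0, camera adjusted p = 1.87e-12), each with adjusted p = 0.711 with an estimated correlation. Fabp1 and Ctsk were the identity genes past the test over all genes, with 9 identity genes lower and 0 cell cycle genes when adjusted over the list alone. Type I interferon genes (median 0.87, SD 1.16, 15 of 17 above 0), monocyte markers (1.20, SD 0.61, 8 of 8) and interstitial macrophage markers (1.23, SD 0.71, 6 of 6) also passed camera. They had adjusted p = 0.711 each with an estimated correlation, and 4, 1 and 1 members higher when adjusted over the list alone. Library HF2 held high levels of all these lists, and without it the medians were -0.07, 0.19 and 0.44 and the calls were lost, as was the interstitial one without NF3 (1.5). Epithelial (0.38, SD 0.47) and endothelial genes (-0.40, SD 0.33) passed camera as well, with adjusted p = 0.711 and 0.8 with an estimated correlation and no member past either gene adjustment. The epithelial call was lost without NM3 (0.38), NF3 (0.40) or HF3 (0.13), and the endothelial one without NF1 (-0.23), NF3 (-0.39), HF1 (-0.11) or HF2 (-0.16). With the calls kept, medians moved by over 1.5 times for identity genes without HF1 (-0.55), interferon genes without NF2 (0.47), epithelial genes without HF1 (0.59) and endothelial genes without HF3 (-1.10).

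The responses of the sexes were then set against each other, the question in the title of the series. All 8 genes called in males and all 8 called in females had the same direction and an unadjusted p under 0.05 in the other sex. Fabp1, Patj and Ecm1 were called in both, where independent lists would share 0.000902 genes upward and 0.000501 downward. Both contrasts come from 1 fit that shares each gene's variance estimate, so the lists are not independent and these values are a rough reference only. The 141 genes called over both sexes all had the same sign in males and females, as their choice on the average favours. They had a median absolute log2 fold change of 1.16 in males and 0.92 in females, and 95 were larger in males. This does not show a stronger male response. The median absolute difference between the responses of these genes was 0.26, below its median SE of 0.37. The male contrast was also noisier, with a median SE of 0.28 against 0.25 at a mean log2 CPM of at least 1. Over the 11419 genes with a mean log2 CPM of at least 1, male and female log2 fold changes correlated with a Pearson r of 0.26 and a Spearman rho of 0.45, across genes, which are not independent replicates. No gene passed the test of the difference between the responses in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 334 genes at an unadjusted p under 0.05 where 997 would be expected. DESeq2 called 3 (Gm26244, ENSMUSG00000119012 and ENSMUSG00000119730, named after their values were seen). The count was 1 without NM1 (Gm26244). Of the 141 genes, 4 had an unadjusted p under 0.05 for the difference, Pcx (-1.36 ± 0.43), Baiap2 (-0.88 ± 0.38), Trp53i11 (-1.0 ± 0.41) and Gm20390 (1.06 ± 0.42), picked after their values were seen. The median SE of the difference was 0.38, and 3% of simulated 2-fold and 68% of 4-fold differences were recovered.

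**Figure D4:**
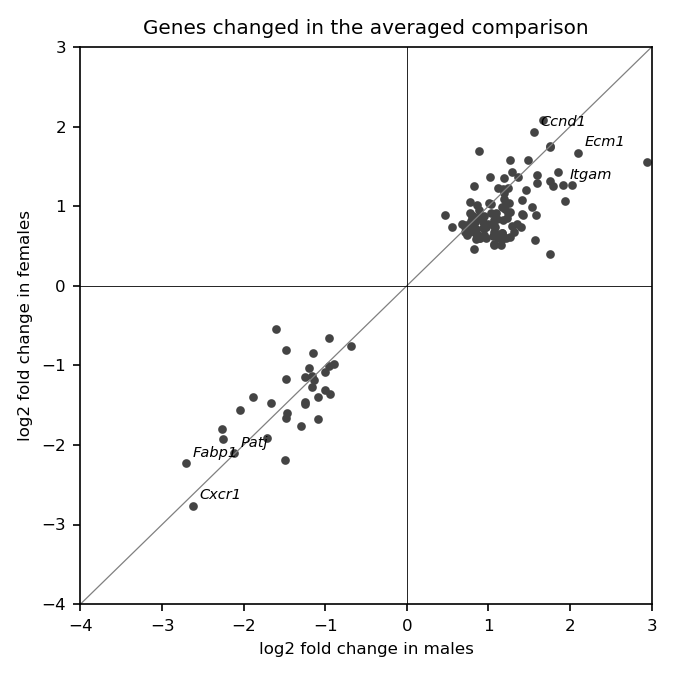
Log2 fold change (hyperoxia over normoxia) in males (x axis) and females (y axis) of the 141 genes called over both sexes, 1 point per gene, with the line of equal change. All points lie on the same side of 0 in both sexes, and 95 are farther from 0 in males, where the estimates were noisier.

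By p, among genes that the naming rule admits, the differences between the responses were led by Entpd4 (2.53 ± 0.65), an enzyme that splits nucleotides, Ptp4a1 (1.13 ± 0.35), Rbm12b1 (1.09 ± 0.36), Nfkbiz (1.26 ± 0.42), a regulator of NF-kB targets, and Hspa1a (2.49 ± 0.83), a heat shock protein, toward females. Ank1 (-1.22 ± 0.32), an ankyrin of the membrane skeleton, Pcx (-1.36 ± 0.43), pyruvate carboxylase, Nnt (-1.41 ± 0.46), a mitochondrial transhydrogenase, Fchsd1 (-1.0 ± 0.35) and Ppp1ccb (-1.20 ± 0.44) led toward males. None passed, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 1.0 for each. The strain C57BL/6 has substrains that differ in Nnt, and the substrain is not given in the sources used here. For gene lists, 5 of 27 passed camera for the difference, and adjusted p = 0.804 for each with an estimated correlation. They were cell cycle, lipid handling, repair and MHC class II genes, lower in the female response, and mesenchyme genes, higher in it, with no member past either gene adjustment. All 5 calls were lost without NM3, with medians of -0.01, -0.20, -0.14, -0.36 and 0.51. The cell cycle call was also lost without NF1 (-0.12), NF2 (-0.17), HM2 (-0.20) or HF1 (-0.20), and the lipid call without NF2 (-0.24) or HF3 (-0.25). Repair genes lost theirs without NM2 (-0.42), NF1 (-0.14), NF3 (-0.22), HM3 (-0.14), HF1 (-0.32) or HF3 (-0.20), and MHC class II genes without NM2 (-0.38), NF3 (-0.27), HM2 (-0.34) or HF1 (-0.37). For mesenchyme genes it was lost without HM3 (0.52). Calls were kept with medians moved by over 1.5 times without NM1 for cell cycle (-0.35), repair (-0.64) and MHC class II genes (-0.56), without NM2 for lipid handling genes (-0.62), without NF3 for cell cycle genes (-0.32), without HM2 for repair genes (-0.42) and without HF3 for mesenchyme genes (0.51).

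Females were compared with males in normoxia. The 5 genes past the test were Xist and the 4 Y-linked genes, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 2.28e-09 for Ddx3y to 1.64e-05 for Kdm5d. An unadjusted p under 0.05 was found for 724 genes. Not past it came Pcx (1.33 ± 0.30), Zc3h12d (1.08), Kdm6a (0.85), a histone demethylase known to escape X inactivation, Ankrd26 (0.89) and Atp2b4 (0.99), higher in females. Lower in females were Rn7s6 (-1.95 ± 0.38), Snord82 (-1.48), Snhg20 (-1.05), Hist1h2ad (-1.11) and Snord21 (-1.51), with adjusted p of the same edgeR quasi-likelihood test from 0.289 to 0.851. The Y-linked list (camera adjusted p = 1.28e-22) and the X inactivation and escape list (median 0.65, camera adjusted p = 3.73e-06) passed, with adjusted p = 0.00129 and 0.0145 with an estimated correlation. Over all genes 4 Y-linked genes and 1 X-linked gene passed, and 4 each when adjusted over the list alone. Cell cycle (median 0.18), lipid handling (0.36, 15 of 17 above 0) and neutrophil genes (0.09) were higher and mesenchyme genes (-0.52) lower by camera. Their adjusted p was 0.914, 0.914, 0.4 and 0.914 with an estimated correlation, with no member past the test over all genes and 3 neutrophil genes higher when adjusted over the list alone. Without NM3 all 4 of these calls were lost (-0.03, 0.20, 0.27 and -0.06). Further losses were the cell cycle call without NF1 (0.08), NF2 (0.09) or HF2 (0.17) and the lipid call without NF2 (0.24), the neutrophil call without NM2 (0.00) or NF3 (0.43), and the mesenchyme call without NM1 (-0.56), NF2 (-0.30), NF3 (-0.57) or HF2 (-0.49). With the calls kept, medians moved by over 1.5 times for cell cycle genes without NM1 (0.30), for lipid handling genes without NM2 (0.55) or NF3 (0.55) and for neutrophil genes without NM1 (0.28), NF1 (0.24) or NF2 (0.28). The gene count was 12 without NF3.

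After hyperoxia, Xist and the 4 Y-linked genes were again the 5 genes past the test between females and males, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 5.64e-09 for Ddx3y to 5.22e-05 for Kdm5d. An unadjusted p under 0.05 held for 345 genes. Among genes not past it, Entpd4 (2.20 ± 0.51), Mid1 (0.95), Kdm6a (0.84), Tfrc (0.78), the transferrin receptor, and Rbm12b1 (0.73) were higher in females. Ank1 (-1.27 ± 0.24), Dscam (-1.28 ± 0.26), Fam124a (-1.03), Wnt7b (-1.33) and Ccl17 (-2.36 ± 0.57), a chemokine, were lower, with adjusted p of the same edgeR quasi-likelihood test of 0.173 or more. The Y-linked list (camera adjusted p = 2.47e-34) and the X list (median 0.70, camera adjusted p = 6.26e-10) passed, also with an estimated correlation (adjusted p = 0.000321 and 0.00328). Interferon genes were higher (median 0.69) and oxidative phosphorylation (-0.21), repair (-0.24) and MHC class II genes (-0.25) lower by camera. Their adjusted p was 0.799, 0.799, 0.558 and 0.799 with an estimated correlation, with no member past the test over all genes, and 1 repair gene lower when adjusted over the list alone. Without HF2 the interferon median was 0.01 and that of oxidative phosphorylation -0.16, and both calls were lost. Calls were also lost without HM2 for oxidative phosphorylation (-0.04) and MHC class II (-0.21), and without HM3 for interferon (0.83) and repair (-0.13). They were also lost without HF1 for repair (-0.33) and MHC class II (-0.22), and without HF3 for repair (-0.17). Medians moved by over 1.5 times, with the calls kept, for interferon genes without HF3 (1.08), oxidative phosphorylation genes without HM3 (-0.41) and MHC class II genes without HM3 (-0.38) or HF2 (-0.62). The gene count was 8 without HM2 and 8 without HF1.

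Averaged over the oxygen groups, Xist was higher in females (9.63 ± 0.46) and Ddx3y, Eif2s3y, Kdm5d and Uty lower, and no other gene passed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 1.23e-11 for Ddx3y to 2.19e-07 for Kdm5d), with 652 genes at an unadjusted p under 0.05. The X inactivation and escape list lay above 0 in 9 of 9 members (median 0.62, camera adjusted p = 7.77e-11, and adjusted p = 0.00248 with an estimated correlation), with 1 member past the test over all genes and 5 when adjusted over the list alone. Further genes are those of smallest p that did not pass and that the naming rule admits (mean log2 CPM of at least 1, predicted genes passed over). Toward females these were Kdm6a (0.85 ± 0.17), Kdm5c (0.86 ± 0.23) and Eif2s3x (0.62 ± 0.18), X-linked genes known to escape inactivation, with Ankrd26 (0.66) and Sema3e (0.53). Toward males they were Rn7s6 (-1.5 ± 0.28), Dscam (-0.87 ± 0.17), Srrm3 (-0.85 ± 0.17), Wnt7b (-1.0 ± 0.21) and Vsig8 (-1.02 ± 0.22). For both directions the edgeR quasi-likelihood, Benjamini-Hochberg adjusted p ran from 0.154 to 0.747. Oxidative phosphorylation genes had a median of -0.20 (SD 0.14, 1 of 20 above 0, camera adjusted p = 0.00613), with adjusted p = 0.989 with an estimated correlation and no member past either gene adjustment. That call was lost without NM1 (-0.10), HM2 (-0.10) or HF2 (-0.16). B cell markers were lower (median -0.45, 1 of 7 above 0, camera adjusted p = 0.0277, and adjusted p = 0.989 with an estimated correlation). Neutrophil markers were higher (median 0.08, 7 of 9 above 0, camera adjusted p = 0.0128, and adjusted p = 0.241 with an estimated correlation). In both lists 0 genes passed over all genes, and 3 neutrophil genes were higher when adjusted over the list alone. The B cell call was lost without NM1 (-0.33), NM3 (-0.04), NF1 (-0.33), NF3 (-0.55), HM3 (-0.36) or HF2 (-0.40), and the neutrophil call without NM2 (0.21), NM3 (0.08), NF3 (0.14) or HM3 (0.11). With the call kept, the B cell median was -0.69 without NM2. The neutrophil median, also with its call kept, was 0.23 without NM1, 0.20 without NF1, 0.18 without NF2, 2.55 without HM2, 0.16 without HF1, 0.12 without HF2 and 0.20 without HF3. The gene count was 8 without NM3 and 14 without NF3, and the Y-linked list passed with camera adjusted p = 3.03e-30 and adjusted p = 0.000492 with an estimated correlation.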

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

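The fit with a term for the 4 libraries with most genes detected (NM3, NF3, HF2, HF3) and the fit without them were chosen after the results were seen. Camera's test of the difference between the female and the male response to hyperoxia singled out 5 gene lists. Cell cycle genes had a median difference of -0.21 (2 of 24 members above 0, camera adjusted p = 0.0141). For lipid handling genes, such as those of fatty acid synthesis and transport, it was -0.36 (1 of 17, camera adjusted p = 0.0104). Repair genes had -0.25 (5 of 17, camera adjusted p = 0.0453), and Ccl17 was their member of smallest p (-1.97 ± 0.76). MHC class II genes had -0.37 (3 of 12, camera adjusted p = 0.0114), with H2-Eb1 at -1.19 ± 0.48. Mesenchyme markers had 1.03 (8 of 9, camera adjusted p = 0.00325). Dcn, a matrix proteoglycan and their member of smallest p, had 0 to 13 counts in a library, at or under the floor in every normoxia female and hyperoxia male library, so no fold is given for it. No member of the 5 lists passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and adjusted p = 0.804 for each list with an estimated correlation.

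All 5 differences were lost without NM3 (cell cycle -0.01, lipid handling -0.20, repair -0.14, MHC class II -0.36, mesenchyme 0.51). Cell cycle also lost its call without NF1 (-0.12), NF2 (-0.17), HM2 (-0.20) or HF1 (-0.20), and lipid handling without NF2 (-0.24) or HF3 (-0.25). Repair lost it without NM2 (-0.42), NF1 (-0.14), NF3 (-0.22), HM3 (-0.14), HF1 (-0.32) or HF3 (-0.20). MHC class II lost it without NM2 (-0.38), NF3 (-0.27), HM2 (-0.34) or HF1 (-0.37), and mesenchyme without HM3 (0.52). With the call kept, the median moved by over 1.5 times without NM1 for cell cycle (-0.35), repair (-0.64) and MHC class II (-0.56), and without NM2 for lipid handling (-0.62). It did so too without NF3 for cell cycle (-0.32), HM2 for repair (-0.42) and HF3 for mesenchyme (0.51). Without NM3, NF3, HF2 and HF3 together, with HF1 alone for hyperoxia females, the mesenchyme median was 0.01, and with a term for these libraries the cell cycle median was 0.05.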

How the results depend on the processing

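The term for the 4 libraries with most genes detected, the fit without these libraries, protein-coding genes only, the length-dependent offset and the exact permutation of list levels were chosen after the results were seen. No named gene that passed the test turned its direction under any alternative. Over both sexes, Ecm1, Cd276, Itgam, Atp2a3, Fabp1, Patj, Ucp3 and Ctsk, 8 of the 28 named genes called, passed in all alternatives, against 0 of 8 in males and 0 of 8 in females. Xist and the 4 Y-linked genes passed in all alternatives, except that Kdm5d after hyperoxia was lost in 1 and that Xist does not enter the fit of protein-coding genes. Size factors of DESeq2 in place of TMM kept each gene count within 1.5 times. The cause of the moves below was not tested, except that protein-coding genes only and fits on fewer libraries change what enters the test.

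Without a filter on low counts, the genes changed with hyperoxia numbered 83 in males, 96 in females and 302 over both sexes. Between the sexes they numbered 30 in normoxia, 40 in hyperoxia, 62 on average and 6 for the interaction. The DESeq2 Wald test gave 83, 84 and 429 for hyperoxia, 15, 24 and 39 for sex and 3 for the interaction, with all 141 genes among the 429. Fitting only the 2 groups compared gave 34 genes in males, 14 in females and 20 between the sexes in hyperoxia. With the detection term, counts were 51, 21 and 501 for hyperoxia and 11 for sex on average. Without the 4 libraries, with HF1 alone for hyperoxia females, they were 16 (4 higher, 12 lower), 2 (both lower) and 23 (10 higher, 13 lower) for hyperoxia, 11 for sex in normoxia and 1 for the interaction (Zfp969, named after its values were seen). The 2 female genes were Zfp969 and ENSMUSG00002075931. Protein-coding genes only gave 16, 22 and 225 for hyperoxia, and the length offset 27, 19 and 313, with 8 for sex on average, where Kdm6a (0.73), Dscam (-1.0) and Gm9794 (1.08) were added.

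With 1 library left out, counts ran from 0 to 19 in males, 0 to 24 in females and 36 to 195 over both sexes. For sex they ran from 5 to 12 in normoxia, 5 to 8 in hyperoxia and 5 to 14 on average, and from 0 to 1 for the interaction. Where HM2 or HM3 was left out, the lone male hyperoxia library was assumed to vary like the other groups, and so was HF1, the lone female hyperoxia library, without the 4 libraries.

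For gene lists, the correlation estimated from the data and fry each left 0 of 9 in males, 0 of 7 in females, 0 of 11 over both sexes, 2 of 6 for sex in normoxia, 2 of 6 in hyperoxia, 2 of 5 on average and 0 of 5 for the interaction. The 2 lists kept were the Y-linked and the X inactivation and escape lists. No filter gave 15 lists in males. Without the 4 libraries, 4 lists passed in females and 3 over both sexes, and with the detection term 2 for sex in hyperoxia and 2 for the interaction. The exact two-sided permutation of list levels over 200 arrangements, whose smallest p is 0.005, left 0 lists over both sexes and 0 for sex on average. In this exact permutation test, cell cycle genes and p53 targets in hyperoxia had p = 0.005 (adjusted p = 0.0675). Identity genes had p = 0.01 in the same permutation test (adjusted p = 0.09). For sex, Y-linked and X-linked genes had p = 0.005 in that permutation test (adjusted p = 0.0675). Even the Y-linked list, whose genes followed the sex labels in every library, thus failed after adjustment at the smallest p possible. The permutation therefore cannot decide about lists that reached p = 0.005, and its 0 lists do not count against them. With 1 library left out, list counts ran from 5 to 14 in males, 4 to 12 in females, 8 to 13 over both sexes, 3 to 9 for sex in normoxia, 6 to 9 in hyperoxia, 3 to 7 on average and 2 to 8 for the interaction. By the direction of camera's test, the lists that turned were cell cycle genes for sex in normoxia (median -0.0344 without NM3, to 0.295 without NM1) and for the interaction (-0.354 without NM1, to -0.0148 without NM3). With the detection term the cell cycle median for the interaction was 0.0506, and without the 4 libraries that of mesenchyme genes was 0.0101. The median alone turned sign for type I interferon genes without HF2 (-0.0175 over both sexes and -0.0672 in females) and, over both sexes, without the 4 libraries (-0.00123). In females, without the 4 libraries, it also turned for epithelial (-0.0213) and interstitial macrophage genes (-0.178), with HF1 the 1 hyperoxia library.

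With the replicate number as a block, counts of genes were 21 in males, 23 in females and 256 over both sexes (138 of the 141 among them), and 10 for sex in hyperoxia and 9 on average. Of 15 pairs of libraries with the same number in different groups, 7 had deviations correlated above 0.1 (lowest -0.32, median 0.0996). Of 30 pairs with different numbers, 13 did (lowest -0.61, median 0.0123). Among the 11 libraries, 6 correlated best with their own number. Deviations of HM2 and HM3 mirror each other (-1), since their group has 2 libraries, and the lowest same-number value is that of NF3 with HM3. These values do not decide whether libraries of the same number share a batch. The main fit, fixed beforehand, did not take the numbers as pairs.

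Depth limits low genes most, since the floor of 3 counts lay between 0.0880 and 0.160 CPM. Of simulated 2-fold differences between the responses of the sexes, 3% were recovered.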

Other observations

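The tests of gene detection, of dilution, of monocytes and of neutrophils, and the length-dependent offset, were chosen after the results were seen. Library HF2 stood apart in interferon and monocyte genes. Ifit3, an antiviral protein induced by interferon, stood at 9.21 CPM in HF2 and at or below 0.755 CPM in the other libraries, and Oasl2, of the same response, at 13.2 against at most 2.32 CPM. Ly6c2, a marker of monocytes, stood at 5.72 against at most 1.1 CPM, and Timd4, a receptor for dying cells, at 4.93 against at most 0.549 CPM. The mean centred level of the interferon list was 1.59 in HF2 and at most 0.07 elsewhere. Erythroid genes stood apart in other libraries, at 2.37 in NM1, 1.39 in NM3 and 1.85 in NF3, and at most 0.44 in the rest.

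Ngp, a protein of neutrophil granules, stood between 0.462 and 3.88 CPM in 5 female libraries, at 0.0587 CPM in HF2 and between 0 and 0.160 CPM in the males, which is at or under the floor, so no fold is given. S100a9, of the same cells, stood between 0.411 and 3.19 CPM in females and between 0.0833 and 0.374 CPM in males. Neither passed over all libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.295 and 0.496), and Ngp passed without HF2 (adjusted p = 0.0241 in the same edgeR test).

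For the 141 genes changed with hyperoxia over both sexes, 3 technical explanations were weighed. With a term for the 4 libraries with most genes detected, 138 of the 141 stayed past the test in the same direction. However, NM3 and NF3 on the normoxia side balance HF2 and HF3 on the hyperoxia side in this average. The term could therefore hardly move the fold changes, and the 138 are no test of gene detection as a cause. With a length-dependent offset, 130 of the 139 with a known exon length stayed, which argues against transcript length as the whole cause. In 4 of 100 splits of the libraries, the real one included, as many genes passed. The real split gave 141 and the highest other 4335. The 100 were drawn from 200 possible splits, and a share of 4 in 100 is borderline, so chance is not excluded for the count. The splits with more genes put all or none of NM3, NF3, HF2 and HF3 on one side, a structure of the samples that the groups do not explain. Other splits that did so gave 0 or 1 gene, so these 4 libraries alone do not account for the high counts. Chance, an effect of oxygen on the cells, and any difference in handling between the oxygen groups, stay open.

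Alveolar macrophage markers after hyperoxia were weighed against other cells in the sort, whose surface markers are not given in the sources used here. Dilution by cells that lack the identity genes would lower them all alike. Their median was -0.32 over all 26 and -1.44 over the 6 that passed, with Itgax at -0.06 and Mrc1 at 0.01. The 6 were picked for their change, so their median lies below that of the list whatever the cause. Whether the other cells hold Itgax or Mrc1 was not tested, so dilution is not decided. Monocytes would bring their other transcripts along with Itgam. Without HF2, the library with the highest monocyte markers, the 4 monocyte markers at a mean log2 CPM of at least 1 had a median of 0.39 (SD 0.43), and all 8 of 0.36 (SD 0.37, 7 above 0), against 1.43 ± 0.20 for Itgam. The most abundant, Ccr2, stood at 43.3 and 33.2 CPM in hyperoxia males and females against 23.6 and 30.3 CPM in normoxia. Itgam stood at 15.7 and 26.2 CPM in normoxia males and females, so a high start alone does not explain the smaller move of Ccr2. How much Itgam monocytes hold for each Ccr2 transcript was not measured here, so these values do not decide about monocytes. Neutrophils hold far more S100a8 and S100a9 than Itgam, yet without HF2 Itgam was higher by 43.7 ± 9.66 CPM in males and 24.1 ± 7.07 CPM in females (SE of the difference of means), S100a8 by 3.50 ± 0.823 and 4.19 ± 3.06 CPM and S100a9 by 0.0665 ± 0.0849 and 0.325 ± 1.43 CPM, which argues against neutrophils as the whole source, though another neutrophil marker, Mmp8, was higher by 13.9 ± 3.83 and 10.1 ± 2.49 CPM. The most abundant neutrophil marker, Csf3r, was lower, at 17.9 and 13.2 CPM in hyperoxia males and females against 28.8 and 36.7 CPM in normoxia. Of the 9 neutrophil markers, 5 lay above 0 without HF2. A shift in the state of the macrophages is an untested hypothesis for the identity genes, beside dilution, and for the rise of Itgam, beside other cells that carry it. It may include monocyte-derived macrophages that hold less of the identity genes, which was not tested either.

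Oxidative phosphorylation genes had a female minus male median of -0.20 on average, which passed camera with the preset correlation (adjusted p = 0.00613) but not without NM1 (-0.10), HM2 (-0.10) or HF2 (-0.16). It had adjusted p = 0.989 with an estimated correlation and p = 0.235 in the exact two-sided permutation of the list level (adjusted p = 0.939), so whether there is a difference is itself open. These genes have a shorter total exon length (median 2593 nt) than the 11254 tested genes with a known length and a mean log2 CPM of at least 1 (4479.5 nt). Across those 11254 genes, which are not independent replicates, the female minus male log2 fold change rose with exon length (Spearman rho 0.47). With a length-dependent offset the median was -0.13 (camera adjusted p = 0.00591 with the preset correlation). Transcript length and an effect of sex cannot be told apart, since part of the median went with the offset and part stayed.

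Other splits bear on the other counts. For sex on average, 4 of 100 splits, the real one included, gave as many genes (5 in the real split, 5047 in the highest other). These too were drawn from 200 possible splits, and the share lies close to 0.05, so chance is not excluded for the count. The count does not use which genes passed, here Xist and the 4 Y-linked genes. The highest split again put NM3, NF3, HF2 and HF3 on one side, though other splits that did so gave 0 to 8. For gene lists chance cannot be excluded either: 24 of 100 splits gave as many for hyperoxia (11 real, 16 highest other) and 84 of 100 for sex (5 real, 16 highest other). Within females and within normoxia the 10 splits are too few for a share under 0.05. For females the real split gave 8 genes (highest other 1) and 7 lists (highest other 11). For normoxia it gave 5 genes (highest other 4918, NM2, NF1 and NF2 against NM1, NM3 and NF3) and 6 lists (highest other 13).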
